A study of Mus musculus with 20 samples.

How the data were processed

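Total RNA from 20 skin samples of FVB/N mice was measured, 5 in each of 4 groups. Per the labels' protocols, RNA was extracted with the Qiagen miRNeasy kit, small RNA libraries were made with a NEBNext set for the SOLiD system and size-selected on acrylamide gels, and they were sequenced on the Applied Biosystems SOLiD instrument, which reads colour-coded bases. The deposited table holds whole-number counts of reads per small RNA feature and library, not normalized. Per the submitters' processing notes the genome build was mm9. The aligner, the counter, the treatment of reads that match several places and the annotation releases are not given in the sources used here. Reads of near-identical miRNAs may therefore have been shared or split, so that members of the miR-101, miR-199, miR-297, miR-466, miR-467 and miR-669 families are uncertain one by one. The same holds for other close relatives, such as let-7 members, miR-133a-3p with miR-133b-3p, and miR-204-5p with miR-211-5p. Further such pairs are miR-29a-3p with miR-29c-3p and miR-181c-5p with miR-181d-5p. Counts of changed list members may thus rest partly on the same reads. No feature has a total under 21 counts, so features with fewer may have been removed before deposit. The table lists 2127 features: 1137 mature miRNAs, 35 further entries of the miRNA class, 388 tRNA entries from UCSC, 353 snoRNAs, 71 piRNAs, 52 snRNAs, 22 mitochondrial tRNAs, 20 rRNAs and a few of other classes. Every column was matched to a sample by its title, and samples were grouped by the stage given in the labels. All columns carry the same prefix and no batch is named in the labels.

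Mature miRNAs were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with its quasi-likelihood F test. Counts were filtered by group with filterByExpr at its defaults, which left 850 of 1137 miRNAs. It asks for at least 15 counts in all and, in the needed libraries, a level that equals 10 counts at the median library size. Shallower libraries thus pass with fewer counts. The counts were then scaled by TMM factors, which ranged from 0.637 to 1.67. One model with a term per group was fitted to all 20 libraries, so that the 4 groups share an estimate of the spread, and gave 6 comparisons between pairs of groups and 1 test across the 4 groups. Log2 fold changes are given with standard errors (SE) derived from the F statistic, and p-values are adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Levels are CPM (counts scaled to library size with TMM factors), as mean ± SD over 5 libraries. The tests were two-sided.

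The 19 miRNA lists (cell type markers, families, imprinted loci, miRNAs raised or lowered in carcinomas in other studies, and a list of miR-193 and miR-365 chosen by the study) were fixed before the data were examined, as were the tests, the alternatives and the rule for named miRNAs. The carcinoma lists rest on general knowledge of the field. The list of miR-193 and miR-365 was the study's own choice, so its falls in these data are not independent evidence of its direction. The 18 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over all lists and comparisons, and again with an estimated correlation. Calls "adjusted over the list alone" use the members' p-values by themselves. The named miRNAs are, in each of the 4 main comparisons, the 8 largest changes each way among miRNAs past the threshold with at least 50 CPM in 1 group, up to 2 further called members of each list, in the 2 secondary comparisons the 3 largest each way, and in every comparison the 5 most abundant miRNAs with miR-21, miR-31, miR-203, miR-205, miR-193b and miR-365. Members of lists that fall outside this rule, such as miR-146a-5p, were named after their values were seen.

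The script was tested on simulated counts drawn from the tested miRNAs' means, their dispersions and the library sizes, with some miRNAs changed by known folds, which then passed through the filter again. Of miRNAs changed by a log2 of 2, it recovered 95.8% for hyperplastic against healthy skin, 82.3% for papilloma, 91.2% for cSCC and 91.6% for cSCC against papilloma, and of those changed by a log2 of 1 it recovered 56.2%, 33.7%, 38.1% and 37.5%. It called 4 of 585, 5 of 615, 2 of 604 and 4 of 617 unchanged miRNAs. The simulated counts all scaled with depth. Many miRNAs changed at once, so recovery may be lower where few change. A list raised in the simulation was called in each of the 6 comparisons, with 0 other lists called.

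The alternatives chosen then were DESeq2 size factors, no low-count filter, a stricter filter of 50 CPM on average (293 miRNAs), DESeq2 1.42.0, the replicate number as a block, library sizes without the 5 most abundant miRNAs, only the 2 groups compared, a log2 fold change of at least 1, all small RNA features and leaving out each library in turn. Each fit without 1 library was filtered and scaled again and tested 859 to 901 miRNAs. A call lost there may therefore reflect the new filter and scaling as well as the library. After seeing the data, scaling factors from the abundant miRNAs, total-count scaling and the stricter filter for lists were added. Pairs of libraries within a group were checked for duplicates: the chi-square per degree of freedom ranged from 82.7 to 1250 over 40 pairs, so none was counted as the same library. Other splits of the samples were drawn 100 times per comparison. Shares of small RNA classes were compared with exact permutation tests. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).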

Results

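Small RNA was sequenced from skin of FVB/N mice, an inbred albino strain, in the chemical model of skin cancer in which the mutagen DMBA starts tumours and the phorbol ester PMA promotes them. The 20 libraries fall into 4 groups of 5: healthy skin treated with acetone, the solvent, and, from DMBA/PMA-treated mice, hyperplastic skin (thickened, without a tumour), papillomas (benign tumours) and cutaneous squamous cell carcinomas (cSCC). Treatment and lesion thus change together in each comparison with healthy skin and cannot be told apart there. The labels describe the samples as biopsies and do not say that each came from its own mouse, so p-values measure the spread between these samples. The deposited table holds read counts of 2127 small RNA features, of which 1137 are mature miRNAs. The total count per library ranged from 1270588 in papilloma 6 to 10117810 in hyperplastic 7, and the mature miRNA count from 1060615 to 6904298. Papilloma libraries were the shallowest on average, with a mean mature miRNA count of 1833000 ± 615000 (SD, n = 5), against 2382000 ± 530000 in cSCC, 4506000 ± 1460000 in hyperplastic skin and 4023000 ± 882000 in healthy skin (SD, n = 5 each).

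The depth difference bears on scaling. The 590 miRNAs with a mean of at most 20 counts summed to 3698 ± 350 counts per library in healthy skin, 4732 ± 1370 in hyperplastic skin, 4649 ± 530 in papilloma and 4637 ± 913 in cSCC (SD, n = 5 each), although the libraries' miRNA totals differed several-fold. As a share of miRNA counts they made up 0.0948% in healthy skin and 0.289% in papilloma. Of the 850 miRNAs tested, 303 belong to this class. Relative to a scaling on the 293 abundant miRNAs (mean of at least 50 CPM, counts scaled to library size), the main fold changes against healthy skin lie lower by a median of 0.66 (log2) for papilloma, 0.71 for cSCC and 0.09 for hyperplastic skin, and those of cSCC against papilloma by 0.05. Fold changes are given from the fit of all 850 miRNAs. For part of the named miRNAs the value of a fit of the 293 abundant miRNAs alone stands beside it, and values against healthy skin given without it lie lower than in that fit by about these medians.

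**Figure D1:**
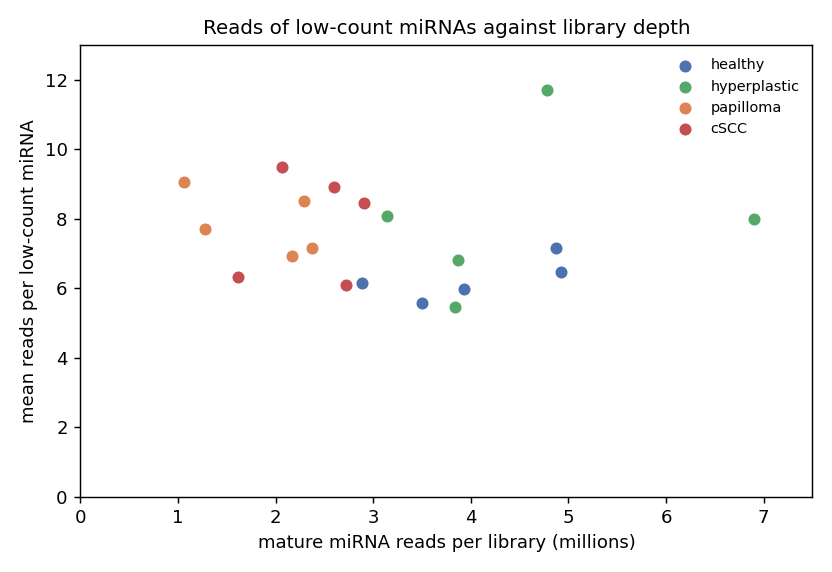
Mean reads per low-count miRNA (mean of at most 20 counts, vertical axis) against the mature miRNA reads of each library (horizontal axis, in units of 1e+06 reads), 1 point per library, coloured by group. The papilloma group has the lowest mean of miRNA reads, and its low-count miRNAs average 7.88 reads, against 6.27 in healthy skin. They average 8.02 reads in hyperplastic skin and 7.86 in cSCC.

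Across the 4 groups, 476 of 850 miRNAs (56%) differed (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05), and 186 of 293 (63.5%) among the abundant ones. The most abundant miRNAs over all libraries were miR-29a-3p with a mean of 112000 CPM, miR-21-5p with 103700, miR-205-5p with 95580, miR-24-3p with 63280 and miR-203-3p with 61540. In healthy skin, miR-205-5p, a miRNA of stratified epithelia, stood at 115000 ± 20300 CPM, and miR-203-3p, which restrains p63 in differentiating keratinocytes, at 75540 ± 22300 CPM (SD, n = 5).

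**Figure D2:**
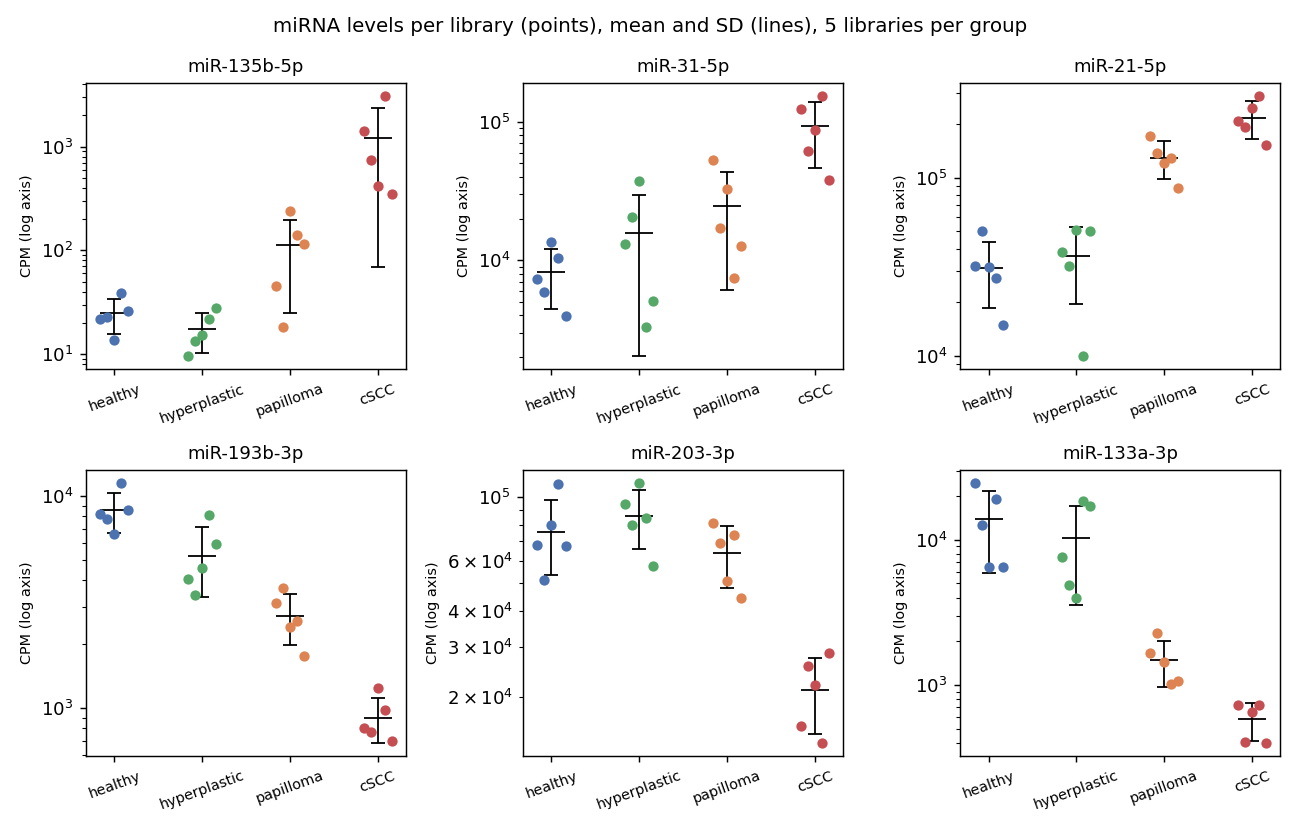
Levels of 6 miRNAs in CPM scaled by TMM factors (vertical log axes) in the 4 groups, 1 point per library, with lines at the mean and 1 SD either side (n = 5 per group). miR-135b-5p, miR-31-5p and miR-21-5p are highest in cSCC, with means of 1201, 92890 and 217800 CPM, and miR-193b-3p is lowest there, with a mean of 896.2 CPM against 8545 in healthy skin.

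The first comparison, hyperplastic against healthy skin, asks what differs in treated skin that is labelled hyperplastic. No single miRNA passed the main test: 0 of 850 passed edgeR's quasi-likelihood test (smallest Benjamini-Hochberg adjusted p = 0.442). In edgeR 75 had an unadjusted p under 0.05, 48 higher and 27 lower. In DESeq2 0 passed, with 85 at an unadjusted p under 0.05. Changes may have been missed, as 56.2% of simulated changes by a log2 of 1 were recovered in this comparison. That simulation held many changes, 89 by a log2 of 1 and 95 by a log2 of 2 among 769 miRNAs. With fewer true changes the adjusted threshold is stricter, so recovery in the real comparison may be lower. The replicate block called 4, all higher, the fit of all features 5, and the fit without healthy 4 called 2. miR-21-5p, which restrains the tumour suppressor Pdcd4, stood at 36300 ± 16900 CPM in hyperplastic and 31110 ± 12700 CPM in healthy skin (log2 fold change 0.22 ± 0.33 SE, adjusted p = 0.866). miR-31-5p, reported raised in squamous carcinomas, had a log2 fold change of 0.94 ± 0.54 (adjusted p = 0.61), and miR-193b-3p one of -0.71 ± 0.26 (adjusted p = 0.442). The levels of miR-203-3p (0.18 ± 0.26), miR-205-5p (-0.11 ± 0.24) and miR-365-3p (-0.44 ± 0.30) did not pass either. Leaving out healthy 7, hyperplastic 5 or hyperplastic 8 turned the estimate for miR-21-5p to -0.07, -0.04 and -0.06. Leaving out healthy 3 or hyperplastic 5 turned that for miR-203-3p to -0.01 and -0.02.

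Of the miRNA lists fixed before the data were examined, camera called 8 in hyperplastic skin although 0 of their members passed, and 12 of 100 splits of the same libraries gave as many. Hyperplastic 7 and 8 lay among the healthy libraries on the first principal component (-13.26 and -12.29, healthy -13.4 to -7.6), apart from hyperplastic 1, 2 and 5 (-6.35, -5.71 and -5.47). The muscle miRNA miR-133a-3p stood at 18380 and 16970 CPM in those 2 and at 3950 to 7566 CPM in the other 3. The miRNAs of the imprinted Dlk1-Dio3 locus had a median log2 fold change of 0.53 over 73 members (camera, adjusted p = 5.89e-15, adjusted p = 0.127 with an estimated correlation). The 3 melanocyte members, arms of miR-204 and miR-211, had one of 1.60 (adjusted p = 0.0118, adjusted p = 0.337 with an estimated correlation). Of those 3, adjusted over the list alone, 2 were higher. The miR-17-92 and miR-34 lists lay higher (medians 0.14 and 0.37, adjusted p = 0.0212 and 0.0383, adjusted p = 0.424 and 0.377 with an estimated correlation). The leukocyte, striated muscle, smooth muscle and carcinoma-lowered lists lay lower (medians -0.39, -0.49, -0.62 and -0.25, adjusted p = 0.0118, 0.0143, 0.0134 and 0.0043). In that order these had an adjusted p = 0.34, 0.424, 0.354 and 0.424 with an estimated correlation. Among abundant miRNAs the leukocyte, miR-17-92 and carcinoma-lowered lists had no call (adjusted p = 0.139, 0.134 and 0.202), and the melanocyte list, with 2 members there, was not tested. The list the study chose, which had no call among all miRNAs (adjusted p = 0.083), lay lower there (adjusted p = 0.0456, adjusted p = 0.437 with an estimated correlation), which is not independent evidence of its direction. The replicate block also called the fibroblast and mesenchyme list lower and the carcinoma-raised list higher (adjusted p = 0.0236 and 0.0299). Without the block these had an adjusted p = 0.771 and 0.459 with an estimated correlation. No list's call held with an estimated correlation in any of the 6 comparisons.

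In papillomas against healthy skin, which asks what differs in the benign tumour of treated mice, miR-31, reported raised in squamous carcinomas, and miR-21 were among the largest rises. miR-31-3p rose from 1221 ± 971 to 7737 ± 4460 CPM (SD, n = 5; log2 fold change 2.66 ± 0.47 SE, adjusted p = 0.000131; 3.23 among abundant miRNAs), and miR-21-5p from 31110 ± 12700 to 129500 ± 30500 CPM (2.06 ± 0.35, adjusted p = 7.85e-05; 2.67). miR-7a-5p, from an intron of Hnrnpk, rose by 2.10 ± 0.43 (adjusted p = 0.000555; 2.71). In all of these each papilloma lay above each healthy library. miR-135b-5p rose by 2.17 ± 0.56 (adjusted p = 0.00395; 2.96), with papilloma 3, at 18.36 CPM, inside the healthy range. Without papilloma 4 its log2 fold change was 1.5 (adjusted p = 0.0405). The deepest falls were in muscle miRNAs: miR-1a-3p fell from 29280 ± 13900 to 2943 ± 2270 CPM (log2 fold change -3.31 ± 0.51, adjusted p = 4.1e-05; -2.70 among abundant miRNAs). miR-133b-3p fell by -3.29 ± 0.50, miR-133a-3p by -3.22 ± 0.44 and miR-206-3p by -3.13 ± 0.63 (-3.98 without papilloma 3).

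In all, 204 miRNAs were higher and 176 lower of 850 (edgeR, adjusted p under 0.05), and 85 higher and 60 lower of the 293 abundant ones. Both fits called 33 higher and 60 lower. Of the 204 and 176, 97 and 3 were low-count miRNAs. The balance of directions changed with the scaling and with the library left out. Fits without 1 library were filtered and scaled again, on 859 to 899 miRNAs here. Dependence on the library and on the filter was thus not told apart. Without papilloma 6 the counts were 99 higher and 182 lower, without papilloma 4 they were 106 and 182, and with the replicate block 110 and 130. Lower calls also outnumbered higher ones without healthy 3, healthy 4, healthy 7 or papilloma 5 (165 to 198 against 137 to 161). Factors from the abundant miRNAs gave 426 higher and 73 lower, and total counts 409 and 74. Library sizes without the top 5 miRNAs gave 137 and 196, and no low-count filter 96 and 211. In 235 of 850 miRNAs the 2 groups' libraries did not overlap, where 0.794% of splits would give this for a miRNA by chance. The depths did not overlap either, with at most 2370313 mature miRNA counts in papilloma and at least 2884177 in healthy skin. This number therefore does not separate depth from the lesion. The other large rises were in miR-1196-5p (2.25), miR-3473d (2.19), miR-3473c (2.05, 1.37 without papilloma 6) and miR-5115 (1.98). The last was 1.18 without papilloma 4 (adjusted p = 0.125) and 2.63 without healthy 5.

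Among the lists, striated muscle miRNAs fell in 8 of 11 tested members, rose in 2 and did not pass in 1 (camera, adjusted p = 0.000126). This list had an adjusted p = 0.312 with an estimated correlation, and 8 falls and 2 rises adjusted over the list alone. The 2 that rose, miR-499-5p and miR-499-3p, had mean counts of 1.6 and 2.4 in healthy skin and 10.2 and 15 in papilloma, too few for a fold. All 4 smooth muscle members fell (adjusted p = 0.00113), among them miR-145-5p by -1.95 ± 0.27 (-1.29 among abundant miRNAs) and miR-143-3p, which had 20850 CPM in healthy skin and 5208 CPM in papilloma. Smooth muscle had an adjusted p = 0.312 with an estimated correlation and 4 falls adjusted over the list alone. miR-145-5p and miR-143-3p lie close together on chromosome 18, with starts at 61807519 and 61808852. The falls in this list need therefore not be independent of each other. The fibroblast and mesenchyme list fell in 17 of 21 (adjusted p = 2.1e-08, adjusted p = 0.303 with an estimated correlation, 17 adjusted over the list alone). Among them was miR-29c-3p, of a family that restrains collagens, at -1.87 ± 0.27 (-1.22 among abundant miRNAs). Both endothelial arms of miR-126, from the Egfl7 gene, fell, miR-126-3p by -1.77 ± 0.33 (-1.13 among abundant miRNAs) and miR-126-5p by -1.06 ± 0.25. The fall of miR-126-5p was not found among abundant miRNAs (-0.40, adjusted p = 0.0904). In the let-7 family, whose members restrain Ras and Hmga2, 13 of 21 fell (adjusted p = 3.01e-05). The let-7 list had an adjusted p = 0.272 with an estimated correlation and 14 falls adjusted over the list alone. By contrast, 5 of 16 fell and 1 rose among abundant miRNAs (list adjusted p = 0.202). The fibroblast and mesenchyme list, in which 7 of 17 fell there, kept its call (adjusted p = 0.00367, adjusted p = 0.481 with an estimated correlation).

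miRNAs that other studies found lowered in carcinomas fell in 22 of 33, rose in 1 and did not pass in 10 (camera, adjusted p = 1.55e-11). They had an adjusted p = 0.127 with an estimated correlation, and 23 falls and 1 rise adjusted over the list alone. Examples are falls of miR-26a-5p (-1.86 ± 0.25; -1.22 among abundant miRNAs) and miR-101a-3p (-2.09 ± 0.33). The Dlk1-Dio3 locus rose in 22 of 73 members and did not pass in 51 (adjusted p = 0.000426), with miR-494-3p at 1.02 ± 0.25 (1.70 among abundant miRNAs), which did not pass with no low-count filter (0.63, adjusted p = 0.0747). This locus had an adjusted p = 0.409 with an estimated correlation and 10 rises adjusted over the list alone. The list the study chose, miR-193 and miR-365, fell in 4 of 6 members (adjusted p = 0.0212), which is not independent evidence of its direction. It had an adjusted p = 0.349 with an estimated correlation and 4 falls adjusted over the list alone. In it, miR-193b-3p fell from 8545 ± 1830 to 2706 ± 728 CPM (-1.66 ± 0.27, adjusted p = 5.49e-05; -1.02) and miR-365-3p by -1.40 ± 0.31 (adjusted p = 0.00104; -0.79). Lists with no call were those of miRNAs raised in carcinomas elsewhere (11 rose, 5 fell of 34), miR-17-92 and paralogues (5 rose, 1 fell of 23) and leukocytes (1 rose, 5 fell of 14). No call was made either for neural and glial cells (1 rose, 3 fell of 15), the miR-200 family (3 fell of 9) or the miR-183 cluster (1 rose, 1 fell of 6). The remaining lists without a call were those of erythroid cells (1 fell of 5), melanocytes (1 fell of 3), the miR-34 family (1 rose of 9), the imprinted H19-Igf2 locus (1 rose of 3) and keratinocytes (0 of 5). For the miR-183 cluster the median and mean were positive and the test pointed down, and for the erythroid list the median alone was positive. Among abundant miRNAs the carcinoma-raised list lay higher (10 rose of 18, adjusted p = 0.00547, adjusted p = 0.222 with an estimated correlation) and the list the study chose lost its call (adjusted p = 0.173). There the keratinocyte, miR-200, miR-183, leukocyte and erythroid tests pointed up instead of down, without a call.

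miR-203-3p (-0.24, adjusted p = 0.432; 0.40 among abundant miRNAs) and miR-205-5p (-0.36, adjusted p = 0.223; 0.28) did not pass and took opposite signs in the 2 fits. The fall of miR-24-3p (-0.60, adjusted p = 0.033) was 0.04 among abundant miRNAs, and its call ended without healthy 2 (-0.61, adjusted p = 0.0668) or healthy 5 (-0.62, 0.0605) and with the replicate block (-0.49, 0.141). miR-31-5p rose by 1.57 ± 0.55 (adjusted p = 0.023; 2.17 among abundant miRNAs, adjusted p = 0.00557). Its call ended without papilloma 1 (0.98, adjusted p = 0.124), papilloma 4 (1.24, 0.0939), healthy 3 (1.41, 0.0586) or healthy 7 (1.32, 0.0654), with the replicate block (1.20, 0.0696) and with no low-count filter (1.19, 0.0778).

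In cSCC against healthy skin, which asks what differs in the malignant tumour of treated mice, miR-135b-5p had the largest rise among miRNAs of at least 50 CPM, from 24.63 ± 9.16 to 1201 ± 1130 CPM (SD, n = 5; log2 fold change 5.60 ± 0.65 SE, adjusted p = 1.87e-07; 6.27 among abundant miRNAs). It was 4.77 without cSCC 4, the highest library at 3081 CPM. miR-31-5p rose from 8259 ± 3830 to 92890 ± 46500 CPM (3.49 ± 0.59, adjusted p = 3.38e-05; 4.15), and miR-21-5p from 31110 ± 12700 to 217800 ± 52100 CPM (2.81 ± 0.36, adjusted p = 6.26e-07; 3.49). miR-147-3p, which Toll-like receptor signals induce in macrophages, rose from 15.83 ± 9.59 to 193.4 ± 71.7 CPM (3.60 ± 0.45, adjusted p = 6.14e-07; 4.34). Among the deepest falls were those of the muscle miRNAs miR-133b-3p (-4.67 ± 0.53; -3.96) and miR-133a-3p (-4.57 ± 0.47; -3.86) and of miR-204-5p, from an intron of Trpm3 (-4.01 ± 0.34, adjusted p = 4.61e-09; -3.28). miR-193b-3p fell from 8545 ± 1830 to 896.2 ± 215 CPM (-3.25 ± 0.28, adjusted p = 4.61e-09; -2.53). miR-203-3p fell from 75540 ± 22300 to 21220 ± 6260 CPM (-1.83 ± 0.26, adjusted p = 4.3e-06; -1.08). In each of these 9 the 5 cSCC libraries lay outside the range of the 5 healthy ones.

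In all, 223 miRNAs were higher and 181 lower of 850 (edgeR, adjusted p under 0.05), and 107 higher and 76 lower of the 293 abundant ones. Both fits called 50 higher and 76 lower. Of the 223 and 181, 82 and 5 were low-count miRNAs. Factors from the abundant miRNAs gave 451 higher and 102 lower, total counts 307 and 145, and no low-count filter 152 and 218. The replicate block gave 143 and 151, and lower calls also outnumbered higher ones without healthy 4 (188 and 201), cSCC 4 (194 and 198) or cSCC 6 (169 and 191). In 251 of 850 miRNAs the 2 groups' libraries did not overlap, where 0.794% of splits would give this for a miRNA by chance. Depth differed here as well, with means of 2382000 mature miRNA counts in cSCC and 4023000 in healthy skin. The number of miRNAs without overlap therefore does not separate depth from the lesion. The other large rises were those of miR-31-3p (3.55), miR-5109 (2.89), miR-34c-3p (2.81) and miR-5115 (2.78, 3.56 without healthy 5). The other large falls were those of miR-133a-5p (-4.19), miR-1a-3p (-4.08), miR-1a-2-5p (-4.07), miR-1a-1-5p (-3.68) and miR-101c (-3.64), whose reads may be shared with its relatives miR-101a and miR-101b.

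miRNAs reported raised in carcinomas rose in 15 of 34 tested members, fell in 1 and did not pass in 18 (camera, adjusted p = 0.00229, adjusted p = 0.303 with an estimated correlation). Adjusted over the list alone, 15 rose and 1 fell. Those reported lowered fell in 24 of 33, rose in 1 and did not pass in 8 (adjusted p = 4.3e-15, adjusted p = 0.127 with an estimated correlation), and 27 fell and 1 rose adjusted over the list alone. Examples are miR-21-3p (2.55 ± 0.29), miR-99a-5p (-2.40 ± 0.25) and miR-99a-3p (-2.90 ± 0.29). The miR-34 family, induced by p53, rose in 7 of 9 (adjusted p = 0.0104, adjusted p = 0.343 with an estimated correlation, 7 adjusted over the list alone). Examples were miR-34b-3p at 2.31 ± 0.40 and miR-34c-5p at 2.08 ± 0.37. The Dlk1-Dio3 locus rose in 21 of 73 (adjusted p = 0.00705, adjusted p = 0.53 with an estimated correlation, 13 adjusted over the list alone). Its examples were miR-494-3p at 2.09 ± 0.26 and miR-541-5p at 1.73 ± 0.26. The list the study chose fell in 4 of 6 (adjusted p = 0.0182, adjusted p = 0.343 with an estimated correlation, 4 adjusted over the list alone). This is again not independent evidence. miR-365-3p fell by -1.63 ± 0.31 (-0.90 among abundant miRNAs).

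Of the lists of other cell types, striated muscle fell in 8 of 11 and rose in 2, the low-count arms of miR-499 (camera, adjusted p = 0.000126, adjusted p = 0.312 with an estimated correlation). Smooth muscle fell in 4 of 4 (adjusted p = 0.00229, adjusted p = 0.322 with an estimated correlation), again falls that need not be independent. The fibroblast and mesenchyme list fell in 16 of 21 (adjusted p = 2.11e-05, adjusted p = 0.343 with an estimated correlation). The let-7 family fell in 14 of 21 (adjusted p = 8.55e-05, adjusted p = 0.303 with an estimated correlation). The melanocyte list fell in 2 of 3 (adjusted p = 0.0183, adjusted p = 0.343 with an estimated correlation). In these 5 lists, adjusted over the list alone, 8, 4, 16, 14 and 2 fell and 2 rose in striated muscle. Among abundant miRNAs let-7 fell in 8 of 16 and rose in 2, and the fibroblast list fell in 6 of 17 and rose in 1. There the calls of the let-7, fibroblast, smooth muscle and miR-34 lists and of the list the study chose were lost (adjusted p = 0.17, 0.101, 0.0936, 0.0883 and 0.0624). The melanocyte member miR-211-5p, from an intron of Trpm1, fell by -2.80 ± 0.61, and by -1.80 without healthy 4. The leukocyte list had no call, with 2 of 14 members higher, 2 lower and 10 that did not pass. Of these, miR-147-3p and miR-223-3p, a miRNA of neutrophils (1.89 ± 0.36, adjusted p = 0.000173; 2.64 among abundant miRNAs), rose. miR-150-5p, of mature lymphocytes (-2.15 ± 0.40), and miR-146a-5p (-1.83) fell.

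The keratinocyte list (3 fell of 5) had no call, nor had the miR-200 family (2 fell of 9), the miR-183 cluster (1 rose of 6), the erythroid (2 fell of 5), neural and glial (2 rose, 3 fell of 15), miR-17-92 (3 rose, 4 fell of 23) and H19-Igf2 (1 rose of 3) lists. Both arms of miR-126 fell, though not among abundant miRNAs (-0.58 and -0.37, adjusted p = 0.0603 and 0.0993). The median was positive and the test pointed down for the miR-200, erythroid and neural lists, whose means were negative. Among abundant miRNAs the miR-200, erythroid and leukocyte tests pointed up. miR-7a-5p of the neural list rose by 2.52 ± 0.44 (1.80 without cSCC 2) and miR-338-3p, from an intron of Aatk, fell by -3.22 ± 0.32. The fall of miR-205-5p (-0.69 ± 0.24, adjusted p = 0.021) was not found among abundant miRNAs (0.03, adjusted p = 0.888). Its call ended without cSCC 2 (-0.60, adjusted p = 0.067), healthy 2 (-0.58, 0.0833), healthy 5 (-0.65, 0.0553) or healthy 7 (-0.65, 0.0538) and with the replicate block (-0.60, 0.0582).

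In cSCC against papilloma, which asks what separates the malignant from the benign tumour, miR-135b-5p rose from 111.3 ± 86.5 to 1201 ± 1130 CPM (SD, n = 5; log2 fold change 3.43 ± 0.59 SE, adjusted p = 0.000337). All 5 cSCC libraries lay above all 5 papillomas, and the value was 2.83 without cSCC 4 and 4.02 without papilloma 4. miR-503-5p rose by 1.76 ± 0.28 (adjusted p = 0.000279), miR-222-3p, which restrains the cell cycle inhibitor p27, by 1.60 ± 0.34 (adjusted p = 0.00238). miR-147-3p rose by 2.09 ± 0.43 and miR-223-3p by 1.53 ± 0.36 (2.33 without papilloma 6). With all features or total-count scaling miR-223-3p did not pass (1.38 and 1.14, adjusted p = 0.0667 and 0.0624). Keratinocyte miRNA miR-203-3p fell from 63780 ± 15500 to 21220 ± 6260 CPM (-1.59 ± 0.26, adjusted p = 0.000279), and miR-193b-3p from 2706 ± 728 to 896.2 ± 215 CPM (-1.59 ± 0.26, adjusted p = 0.000279). miR-211-5p fell by -2.52 ± 0.61, miR-204-5p by -2.29 ± 0.32, and miR-181c-5p and miR-181d-5p by -1.70 ± 0.27 and -1.70 ± 0.31. miR-21-5p (0.75 ± 0.33, adjusted p = 0.179), miR-205-5p (-0.33 ± 0.24, adjusted p = 0.475) and miR-365-3p (-0.23 ± 0.31, adjusted p = 0.743; 0.04 without cSCC 6) did not pass. miR-21-5p did pass with the replicate block (0.81, adjusted p = 0.0315) and with only these 2 groups in the fit (adjusted p = 0.0314), and miR-205-5p with total-count scaling (-0.61, adjusted p = 0.0221).

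Here 58 miRNAs were higher and 40 lower of 850 (edgeR, adjusted p under 0.05), 38 and 36 among the 293 abundant ones. Both fits called 29 higher and 28 lower. Without cSCC 4 the calls were 41 higher and 14 lower, and without papilloma 5 they were 56 and 14. Without any 1 of the other 8 libraries the lower calls numbered 19 to 26 and the higher ones 41 to 66. Total-count scaling gave 32 higher and 77 lower, library sizes without the top 5 miRNAs 66 and 26, and no low-count filter 59 and 21. In 51 of 850 miRNAs the libraries of both groups did not overlap, where 0.794% of splits would give this for a miRNA by chance. Further rises were those of miR-297b-3p (2.44), miR-297a-3p (2.35), miR-669a-5p (2.31) and miR-669m-5p (2.27), which come from 1 cluster on chromosome 2 and whose reads may be shared among near-identical copies. miR-31-5p rose by 1.92 (adjusted p = 0.0225), but its call ended without cSCC 4 (1.78, adjusted p = 0.0501) or papilloma 3 (1.79, 0.0673), and its value was 2.53 without papilloma 1. miR-296-5p rested on cSCC 4: its log2 fold change of 2.96 (adjusted p = 0.0122) was 0.87 without that library (adjusted p = 0.409). The fall of miR-511-3p, from an intron of the macrophage gene Mrc1 (-1.63, adjusted p = 0.0122), lost its call without cSCC 2 (-1.41, adjusted p = 0.0507), cSCC 4 (-1.49, 0.0624), papilloma 3 (-1.29, 0.0635) or papilloma 5 (-1.36, 0.0703).

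**Figure D3:**
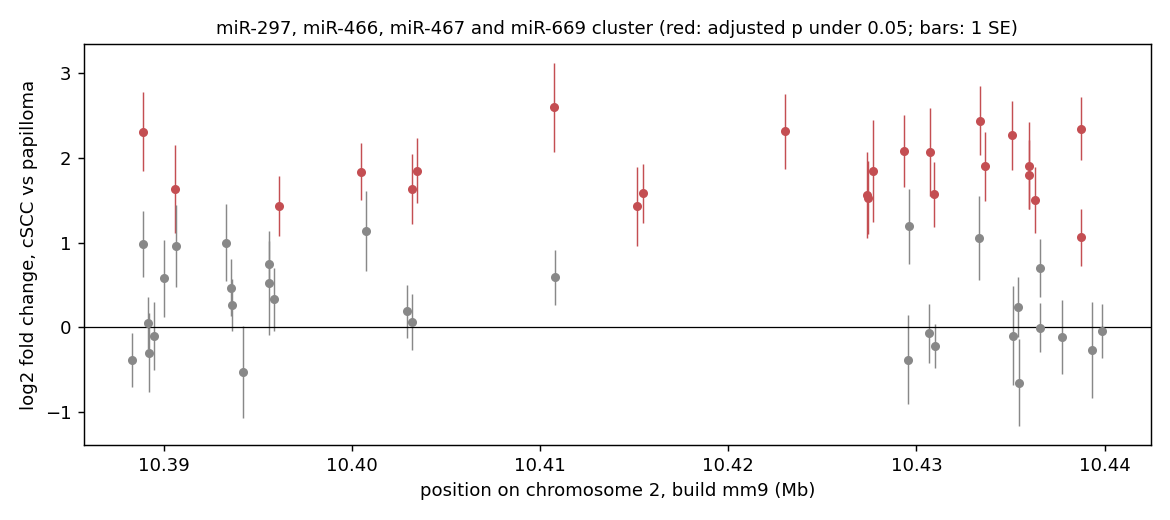
Log2 fold change of cSCC against papilloma (vertical axis, bars 1 SE) of the miRNAs of the cluster against their position on chromosome 2 in Mb of build mm9 (horizontal axis), red where the adjusted p is under 0.05. Of 55 tested members, 24 are higher in cSCC and 0 lower.

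By lists, miRNAs reported raised in carcinomas rose in 9 of 34 and did not pass in 25 (camera, adjusted p = 3e-06, adjusted p = 0.127 with an estimated correlation, 13 adjusted over the list alone). Those reported lowered fell in 13 of 33 and rose in 1 (adjusted p = 9.65e-06, adjusted p = 0.322 with an estimated correlation, 13 and 1 adjusted over the list alone). In the miR-34 family 4 of 9 rose, with miR-34c-5p at 1.79 ± 0.37 (adjusted p = 0.000549, adjusted p = 0.272 with an estimated correlation, 5 adjusted over the list alone). Melanocyte miRNAs fell in 2 of 3 (adjusted p = 0.000426, adjusted p = 0.262 with an estimated correlation, 3 adjusted over the list alone). Keratinocyte miRNAs fell in 2 of 5, both arms of miR-203 (adjusted p = 0.0469, adjusted p = 0.355 with an estimated correlation, 2 adjusted over the list alone). The keratinocyte call was lost with the replicate block (adjusted p = 0.0669) and among abundant miRNAs (adjusted p = 0.0873), where the miR-34 call was lost as well (adjusted p = 0.17). The keratinocyte median was -0.33 over 5 members and -0.86 over the 4 abundant ones. The leukocyte list had no call (adjusted p = 0.109, adjusted p = 0.476 with an estimated correlation), though it had one with the replicate block (adjusted p = 0.0422). In it 3 of 14 were higher: miR-147-3p, miR-223-3p and miR-142-5p (1.65 ± 0.35), the last made in blood cells. Lists without a call were the miR-183 cluster (2 rose of 6), neural and glial (1 fell of 15), erythroid (0 of 5), miR-17-92 (0 of 23) and H19-Igf2 (0 of 3). Nor was a call made for striated muscle (1 fell of 11), smooth muscle (0 of 4), fibroblast and mesenchyme (2 rose, 1 fell of 21), let-7 (1 fell of 21), Dlk1-Dio3 (3 rose of 73) and the list the study chose (1 fell of 6). The single falls in the striated muscle and neural lists, miR-133a-3p (-1.36) and miR-338-3p (-0.98), did not pass when any 1 of the 10 libraries was left out (log2 fold changes of -1.38 to -1.17 with an adjusted p = 0.0625 to 0.122, and of -0.95 to -0.76 with an adjusted p = 0.0825 to 0.218). For the miR-200 family (0 of 9) the mean was positive and the median and test negative, and the endothelial arms numbered 0 of 2.

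The last 2 comparisons set the tumours against hyperplastic skin. Relative to a scaling on the abundant miRNAs, these fold changes lie lower by a median of 0.575 (log2) for papilloma and 0.623 for cSCC. In papillomas, miR-5115 (3.12 ± 0.63, 2.46 without papilloma 4), miR-135b-5p (2.67 ± 0.58, adjusted p = 0.00146) and miR-3473d (2.28 ± 0.30) rose most among miRNAs of at least 50 CPM. The muscle miRNAs miR-133b-3p (-2.81 ± 0.49), miR-133a-3p (-2.80 ± 0.43) and miR-1a-3p (-2.70 ± 0.50) fell most, and 181 were higher and 145 lower of 850 (edgeR). In cSCC, miR-135b-5p (6.10 ± 0.67, adjusted p = 2.22e-07, 5.25 without cSCC 4), miR-5115 (3.92 ± 0.66) and miR-147-3p (3.88 ± 0.46) rose most. There miR-211-5p (-4.40 ± 0.66), miR-133b-3p (-4.18 ± 0.52) and miR-133a-3p (-4.16 ± 0.46) fell most, and 208 were higher and 174 lower. Among the 293 abundant miRNAs the counts were 46 higher and 41 lower in papilloma and 81 and 68 in cSCC. With factors from these miRNAs they were 320 and 48, and 369 and 82, of 850. With total counts they were 245 and 58, and 195 and 148, and with no low-count filter they were 87 and 206, and 140 and 216. The replicate block gave 38 and 44, and 94 and 96. In papilloma the counts were 109 and 122 without papilloma 6, 137 and 87 without hyperplastic 7, and 137 and 168 without hyperplastic 2. In cSCC lower calls outnumbered higher ones without hyperplastic 2 (173 and 188), cSCC 4 (190 and 197) or cSCC 6 (157 and 190). miR-193b-3p fell in cSCC (-2.54 ± 0.27, -1.89 among abundant miRNAs). In papilloma it fell by -0.95 ± 0.26 (adjusted p = 0.00711) in the fit of all miRNAs. This fall did not pass among abundant miRNAs (-0.38, adjusted p = 0.13), without hyperplastic 7 (-0.69, adjusted p = 0.0517) or with the replicate block (-0.68, adjusted p = 0.126). Camera called 6 lists in papilloma and 8 in cSCC, and 0 of them with an estimated correlation.

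The 3 comparisons against healthy skin share their 5 healthy libraries, which alone gives their fold changes a correlation. Across 850 miRNAs, which are not independent replicates, the fold changes of papilloma and cSCC had r = 0.835, where 100 simulations of unchanged groups gave a mean of 0.491. Their covariance was 1.24 against a simulated 0.0838, a difference of 1.16. The comparisons shared 137 miRNAs called higher and 151 called lower, against 53.5 and 37.5 for independent lists and 0 in the simulations, and 0 were called in opposite directions. The simulated counts, here and for hyperplastic skin below, all scale with depth, which those of low-count miRNAs did not. The simulations therefore cannot show how many shared calls depth alone would give. The simulated groups were also unchanged, so hardly any miRNA could be called in them. Their 0 shared calls are thus no measure of the overlap that shared controls add where groups do change. Among the 293 abundant miRNAs r was 0.876, and 76 higher and 51 lower calls were shared, against 31 and 15.6 for independent lists. Over all 850 again, with the healthy libraries split into 2 and 3, r averaged 0.71 over 20 assignments, and 33 to 69 higher and 74 to 117 lower calls were shared. For hyperplastic skin, the correlation with papilloma (0.43, simulated 0.495) and with cSCC (0.317, simulated 0.501) did not exceed the simulated one. The covariances of 0.246 and 0.219 exceeded the simulated 0.0826 and 0.0829 by 0.163 and 0.136. With split controls r averaged 0.213 and 0.147.

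By the coordinates in the deposited table, which are those of mouse build mm9, miR-135b-5p lies on chromosome 1 at 134094679 to 134094703, miR-21-5p on chromosome 11 at 86397621 to 86397644 and miR-31-5p on chromosome 4 at 88556517 to 88556540. miR-193b-3p lies on chromosome 16 at 13449662 to 13449685, miR-203-3p on chromosome 12 at 113369137 to 113369160 and miR-204-5p on chromosome 19 at 22825099 to 22825122. In the GENCODE annotation, used for names only because it is of another build, the miR-135b precursor lies in an intron of Lemd1, miR-21 in an exon of Vmp1, miR-31 in an exon of a long non-coding RNA gene, miR-147 in an exon of AA467197. The miR-193b and miR-203 precursors lie in no other gene.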

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

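The tests of explanations and the counts over other splits of the samples in this part were chosen only after the result was seen. Chance places about 1 in 20 groups of 5 values beyond the limit used here for a library far from the other 4 of its group (gap to the nearest over the range, above 0.71, taken on log2 CPM for miRNAs and on the plain scale for library totals and shares), and 15 of 368 groups of values exceeded it, 4.08%, against 18 by chance.

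In healthy 7 the snRNA share was 0.0495% against 0.019 to 0.0229% in the other healthy libraries (gap over range 0.87). Hyperplastic 7 lay apart in miR-21-5p with 9919 CPM against 31820 to 51050 (0.71 on log2 CPM), in miR-143-3p with 22330 against 9790 to 11780 (0.78) and in miR-126-3p with 18970 against 6265 to 8250 (0.75). Hyperplastic 8 had 12.8 CPM of miR-5115 against 20.5 to 24.2 (0.73) and 0.32 CPM of miR-135b-3p against 0 in the others (1). Papilloma 3 had 80.8 CPM of miR-133a-5p against 44.8 to 52.2 (0.74) and 67.3 CPM of miR-494-3p against 100.4 to 107.4 (0.86). In papilloma 6 miR-223-3p was 57740 CPM against 12540 to 17890 (0.77), and in papilloma 4 miR-101a-5p was 2.87 CPM against 11.8 to 13.9 (0.89). In cSCC 4 miR-3473c was 238 CPM against 602.9 to 845.7 (0.73). cSCC 6 had 106.1 CPM of miR-1a-1-5p against 307.5 to 436 (0.75) and 536.2 CPM of miR-182-5p against 1417 to 2068 (0.72). In cSCC 1 miR-486-5p was 9.32 CPM against 3.91 to 4.53 (0.84), and in cSCC 2 the rRNA share was 1.09% against 0.607 to 0.717% (0.77). Outside the miRNAs, the rRNA share was 0.848% in papilloma against 0.679% in healthy skin, with all 5 papillomas above all 5 healthy libraries (exact permutation p = 0.00794, adjusted p = 0.0333 over all classes and groups).

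Low-count miRNAs made up a larger share of the counts in papilloma and cSCC than in healthy skin, by 1.51 and 1.07 on the log2 scale. Counts that do not scale with depth may account for much of this: within groups, their log2 sum had a slope of 0.08 on the log2 miRNA total (jackknife SE 0.15), where miRNAs over 200 counts had 1.01. With that slope removed, papilloma still lay 0.42 above healthy skin (exact permutation p = 0.00794) and cSCC 0.36 (exact permutation p = 0.0556), a mean of 0.39. At this slope lower depth would lower the sums, not raise them. Expression that changes with the lesion stays open for this remainder, since the difference of cSCC did not pass the 0.05 set for this test. Hyperplastic skin, where 0 miRNAs were called, was not part of this test. Its low-count sum of 4732 ± 1370 counts was no lower than the 4649 ± 530 of papilloma and 4637 ± 913 of cSCC. The remainder was thus not shown to be particular to the tumours.

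Striated muscle miRNAs were lower in papilloma and cSCC. A shift in scaling was excluded as the whole cause, since the 7 members with at least 50 CPM lay between -3.96 and -2.11 in the fit of abundant miRNAs in both comparisons. A smaller share of muscle in the biopsies may contribute: within groups, miR-1a-3p and miR-206-3p, from different transcripts, deviated together with r = 0.67 over 20 libraries (permutation p = 0.001; Spearman's rho = 0.58, permutation p = 0.008; r = 0.63 without the 2 farthest libraries), under the 0.7 set for this test, so it stays open. miR-1a-3p and miR-133a-3p, which have precursors in a shared host gene, had r = 0.55 (rho = 0.57, r = 0.68 without the 2 farthest libraries). As this pair also lay under 0.7, missing that limit does not speak against a smaller share of muscle. A change within the lesion that the stage brings stays open as well and was not tested.

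Over 100 splits per comparison, the real one included, the real grouping gave the most calls for papilloma against healthy skin (380 miRNAs, 1 split as large, highest other 163), cSCC against healthy skin (404, 1 split, 182), cSCC against papilloma (98, 1 split, 41), papilloma against hyperplastic skin (326, 1 split, 138), cSCC against hyperplastic skin (382, 1 split, 103) and the 4 groups (476, 1 split, 221). Chance alone was thus unlikely for these. Depth differed between the groups as well, so the splits do not separate depth from the lesion. For hyperplastic against healthy skin 0 miRNAs were called, so all 100 splits gave as many by construction and their number says nothing about chance. The highest other gave 28: it set hyperplastic 1, 2 and 5 with healthy 3 and 4 against hyperplastic 7 and 8 with healthy 2, 5 and 7. How high the largest of so many splits would lie by chance was not tested. For the lists, adjusted within each comparison, chance was not excluded in any comparison: 8 lists for hyperplastic against healthy skin (12 splits as large, highest other 10), 7 for papilloma against healthy skin (32 splits, 12), 10 for cSCC against healthy skin (8 splits, 12), 4 for cSCC against papilloma (57 splits, 9), 6 for papilloma against hyperplastic skin (30 splits, 11) and 9 for cSCC against hyperplastic skin (12 splits, 12).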

How the results depend on the processing

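Abundant-miRNA scaling, total-count scaling and the stricter filter for lists were chosen after seeing the data, and the other alternatives before. Of 182 named results, 125 kept their direction and side of the threshold under every alternative run, and of 3608 values under alternatives 3351 kept both, 197 no longer passed, 23 newly passed and 37 changed sign. With the stricter filter, which tests fewer miRNAs, the calls numbered 145 for papilloma and 183 for cSCC against healthy skin, 87 and 149 against hyperplastic skin and 186 across the 4 groups. The lists called were then 5 for hyperplastic, 4 for cSCC against healthy skin, 2 for cSCC against papilloma and 3 for cSCC against hyperplastic skin. With an estimated correlation 0 lists were called in each of the 6 comparisons. With the replicate number as a block the calls were 4 for hyperplastic and 240 for papilloma against healthy skin, 82 and 190 for papilloma and cSCC against hyperplastic skin and 304 across the 4 groups. The labels do not say whether the numbers pair the samples. Residuals of 17 pairs with the same number correlated between -0.156 and 0.208. Pairs with different numbers were not set beside them, so a pairing was neither shown nor excluded. All features, which adds other RNA classes, gave 5 for hyperplastic and 675 for cSCC against healthy skin, 639 for cSCC against hyperplastic skin and 821 across the 4 groups. With split healthy libraries the correlations were 0.213 for hyperplastic skin with papilloma, 0.147 for hyperplastic skin with cSCC and 0.71 for papilloma with cSCC. Signs changed under both abundant-miRNA scaling and the stricter filter, whose factors shift all fold changes, for miR-203-3p in papilloma against healthy (0.397) and hyperplastic skin (0.108), miR-205-5p in cSCC against healthy (0.033) and hyperplastic skin (0.052) and in papilloma against the same (0.277 and 0.296). They also changed for miR-24-3p in papilloma against the same (0.037 and 0.077) and miR-29a-3p in cSCC against the same (0.148 and 0.493). Total-count scaling changed the sign of miR-203-3p (0.382) and miR-24-3p (0.022) in papilloma against healthy skin, miR-205-5p in hyperplastic (0.117) and papilloma (0.255) against healthy skin and papilloma against hyperplastic skin (0.138), and miR-24-3p in hyperplastic against healthy skin (0.094). All features changed that of miR-203-3p in papilloma against healthy skin (0.019) and of miR-29a-3p in cSCC against hyperplastic skin (0.073), which the block also changed (0.246). The cause was not tested. Leaving out 1 library gave 0 to 2 calls for hyperplastic, 281 to 374 for papilloma and 360 to 392 for cSCC against healthy skin, 55 to 90 for cSCC against papilloma, 224 to 340 for papilloma and 346 to 400 for cSCC against hyperplastic skin and 444 to 491 across the 4 groups. It gave 5 to 11, 7 to 7, 9 to 10, 4 to 6, 5 to 6 and 8 to 9 lists in the same order of comparisons. It changed signs in hyperplastic against healthy skin for miR-203-3p (-0.009 without healthy 3, -0.017 without hyperplastic 5, range to 0.255) and miR-21-5p (-0.071 without healthy 7, -0.044 and -0.061 without hyperplastic 5 and 8, range to 0.362). It did so for miR-29a-3p in cSCC against hyperplastic skin (0.206 and 0.061 without hyperplastic 7 and 8, range from -0.474) and for miR-365-3p in cSCC against papilloma (0.036 without cSCC 6, range from -0.293). Fits without 1 library were filtered and scaled again, so the part of the library in these changes was not told apart from that of the filter. The 303 low-count miRNAs tested rest on few reads, at most 20 on average.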

Other observations

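The tests of the chromosome 2 cluster in this part were chosen only after the result was seen. The miRNAs of this cluster, in an intron of Sfmbt2 by the GENCODE annotation, lie between 10388303 and 10439868 in build mm9. Of 55 tested members 24 were higher in cSCC than in papilloma and 0 lower (edgeR), 43.6%, against 34 of 795 other miRNAs called higher, with a median log2 fold change of 1. Against healthy skin 46 were higher in cSCC and 16 in papilloma. Their summed level, scaled with factors from the abundant miRNAs, was 4638, 4528, 1383, 4667 and 2508 CPM in cSCC 1, 2, 3, 4 and 6. It was 958 to 2354 CPM in the papillomas, 583 to 821 CPM in hyperplastic and 598 to 870 CPM in healthy skin. This scaling sets papilloma and cSCC higher against healthy skin than the main one, by medians of 0.66 and 0.71 (log2). The highest papilloma sums were those of papilloma 4 and 6 (2354 and 2322 CPM), the shallowest of that group.

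One tumour as the whole cause was excluded, since 18 members or more were called higher whichever cSCC library was left out (18 without cSCC 1 or cSCC 4, 27 without cSCC 3). For cSCC against papilloma, counts that do not scale with depth were excluded too. Counts equal in all libraries would take a log2 fold change of -0.13 ± 0.16 (SE) there, where the median of the cluster was 1. The rises against healthy skin, whose libraries were deeper, were not tested in this way. With factors from the abundant miRNAs 21 members were higher. Of 10 miRNAs of the same families elsewhere in the genome 0 were higher, but reads may be shared among near-identical copies, which was not tested, so a biological change of the cluster in cSCC stays a hypothesis.

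Classes of small RNA other than miRNAs also differed from healthy skin (exact permutation tests, adjusted over all classes and groups). Mature miRNAs took 76.7% ± 2.2 of the counts in cSCC against 67.6% ± 4.73 in healthy skin (SD, n = 5 each; exact p = 0.00794, adjusted 0.0333; all 5 above healthy skin), and tRNA features 20.4% ± 2.13 against 29.3% ± 4.83 (exact p = 0.0159, adjusted 0.0417). These 2 classes take most of the counts, so the lower tRNA share mirrors the higher miRNA share and is not a separate result. In hyperplastic skin snoRNAs took 0.894% ± 0.0951 against 1.2% ± 0.131 (exact p = 0.00794, adjusted 0.0333) and mitochondrial tRNAs 0.619% ± 0.132 against 0.952% ± 0.165 (exact p = 0.0159, adjusted 0.0417). The piRNA share was 0.297% in healthy skin, 0.184% in hyperplastic skin (exact p = 0.00794), 0.201% in papilloma (exact p = 0.0159) and 0.176% in cSCC (exact p = 0.00794).

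The hyperplastic libraries differed among themselves. On the first principal component, which held 57.4% of the variance, hyperplastic 1, 2 and 5 lay at -6.35, -5.71 and -5.47 and hyperplastic 7 and 8 at -13.3 and -12.3, where healthy libraries spanned -13.4 to -7.6, papillomas 0.37 to 9.06 and cSCC 12.5 to 17.3. miR-31-5p stood at 13010, 20480, 37350, 3313 and 5109 CPM in hyperplastic 1, 2, 5, 7 and 8.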
